A study of Mus musculus with 2 samples.

How the data were processed

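RNA sequencing libraries of FACS-sorted ALL211 leukemia cells from the spleens of recipient mice were analysed, 1 library of untreated and 1 of Dox-treated (3 days) animals. Total RNA was prepared with a column kit and libraries by a standard Illumina protocol, per the labels' protocols, and both libraries carry the same batch date. The series design names 2 mice per condition, while the labels give 1 sample per condition; whether RNA of both mice was pooled is not given in the sources used here. The untreated sample is labelled GFP-high and the Dox sample GFP-mid.

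The deposited values are raw read counts per gene, listed by Entrez gene identifier with a gene length column that is an annotation and was used only as a gene property. Per the submitters' processing notes, CASAVA 1.8.2 and featureCounts (version not given) were used with the mm10 build. The aligner, the strand setting, the treatment of reads with several alignments and the annotation are not given in the sources used here. Without a known strand setting, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The table of the whole series held the same counts as the separate sample tables (0 of 27179 genes differed in either library), and 0 columns were left unassigned. Of the 27179 genes, 25293 received a symbol, 25275 from the RefSeq table of the GRCm38 assembly and 18 from a GENCODE annotation; 1886 without a symbol stayed in the totals.

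The totals of 16960042 and 16484613 counts set the precision. A floor of 3 counts corresponds to 0.176 CPM in the untreated and 0.183 CPM in the Dox library. The 10 most abundant genes took 4.37% and 4.28% of counts, and genes without a symbol 1.20% and 0.971%. Counts were scaled with TMM factors (1.01 and 0.994) in edgeR 4.0.16 under R 4.3.3. Log2 folds are differences of log2 CPM with a prior count of 2; plain ratios and CPM carry no prior count. Genes with at least 1 CPM in at least 1 library were kept, 12125 genes, of which 271 had no symbol. With 1 library per condition no test between conditions was possible and no p-value was computed; the planned replicated edgeR comparison was therefore not run. Each ratio has an exact Clopper-Pearson 95% interval from the conditional binomial distribution of the counts, which covers counting error only. A gene with 0 counts in 1 library is given as a bound against the floor of 3 counts per library. Such an "at least" value leaves out the counting error of the other library. It can therefore exceed the smallest fold that the 95% interval allows. Shares of receptor segment counts have Wilson 95% intervals.

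The 35 gene lists, the grouping of samples, the comparison, the rule for named genes and most alternatives were fixed before the data were examined. A list median is described by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with at least 4 measured members; 34 lists had a measured member and 33 a percentile. The percentile describes these libraries and is no test between conditions. Named genes are Ikzf1; among genes with at least 5 CPM in 1 library and an interval wholly beyond 2-fold (1641 genes), the 15 highest and 15 lowest, passing over predicted or clone names, names without a symbol and ribosomal RNA; up to 4 members of each list with the largest absolute log2 fold, and for lists of other cell types also the 2 most abundant; and always Hes1, Dtx1, Notch3, Ptcra, Il2ra and Myc. Some genes that this rule names are not reported here.

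Alternatives were total-count, DESeq2 1.42.0 median-of-ratios and upper quartile scaling, prior counts of 0.5 and 5, filters of at least 1 count and at least 5 CPM, thinning of the deeper library, totals without 193 mitochondrial, ribosomal and haemoglobin genes or without 124 genes of other cell types, a 4-fold threshold, the counting interval in place of the point estimate, 10 expression bins and matching on the untreated level. Removal of lowess trends with gene length or GC content, and matching on expression and length, were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9. The steps were tested on Poisson counts simulated for this comparison over 11882 genes, 200 of them changed. Of simulated 2-fold genes, 62% came out at least 2-fold, of 4-fold genes 98%, of 8-fold genes 100% and of unchanged genes 0.317%. Intervals covered the true ratio for 92% to 98% of the changed genes, and 4.5% of 200 random lists fell outside the central 95%. The simulated counts held counting error only, with each gene drawn independently. These rates therefore check the calculation and do not measure differences between mice or sorting gates, or genes regulated together.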

Results

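Gene expression was measured by RNA sequencing in ALL211, a primary mouse T-cell acute lymphoblastic leukemia (T-ALL) carrying Vav-tTA and TRE-GFP-shIkaros. In this system a tetracycline-controlled transactivator drives a short hairpin RNA against Ikaros together with GFP, and doxycycline (Dox) turns both off. The comparison asks how the transcriptome of these leukemia cells differed once endogenous Ikaros, a zinc finger transcription factor of lymphoid cells, was allowed to return. Leukemia cells were sorted from the spleens of recipient mice. The untreated group (n = 1 library) was sorted as GFP-high cells, and the group given Dox for 3 days (n = 1 library) as GFP-mid cells. The untreated library held 16960042 counts over 15487 genes, and the Dox library 16484613 counts over 15995 genes.

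Each condition had 1 library, so the differences have no replicate check and no p-value is given. The intervals below are 95% intervals of the ratio of counts and cover counting error only. They treat reads as independent, which PCR copies of a molecule are not, so they may be too narrow even for that error. Treatment, sorting gate and mouse all differed between the libraries, and Dox without the hairpin was not analysed here.

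Ikzf1 (Entrez 22778; GRCm38 chromosome 11, 11684962 to 11772930), the gene that encodes Ikaros, was 10.2-fold higher in the Dox library. Its level was 120.5 CPM (counts scaled to a common library size) in the untreated library and 1229 CPM in the Dox library, from 2057 and 20131 counts (log2 fold 3.35, interval 3.29 to 3.42). The library labelled as Dox treated thus held more of the targeted transcript, the direction its label gives. The other Ikaros family members differed less. Ikzf3, which encodes Aiolos, had a log2 fold of 0.93, Ikzf2, which encodes Helios, 0.92, and Ikzf5 0.33. Of the 5 measured family genes, 1 was at least 2-fold higher and 0 were at least 2-fold lower.

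Across the 12125 genes with at least 1 CPM in at least 1 library, 1644 (13.6%) were at least 2-fold higher in the Dox library and 1581 (13.0%) at least 2-fold lower, while 8900 lay within 2-fold. The median log2 fold of all these genes was -0.01. The counting interval lay wholly beyond 2-fold for 1105 of the genes higher and 1016 of those lower. At least 4-fold, 541 genes were higher and 372 lower.

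**Figure D1:**
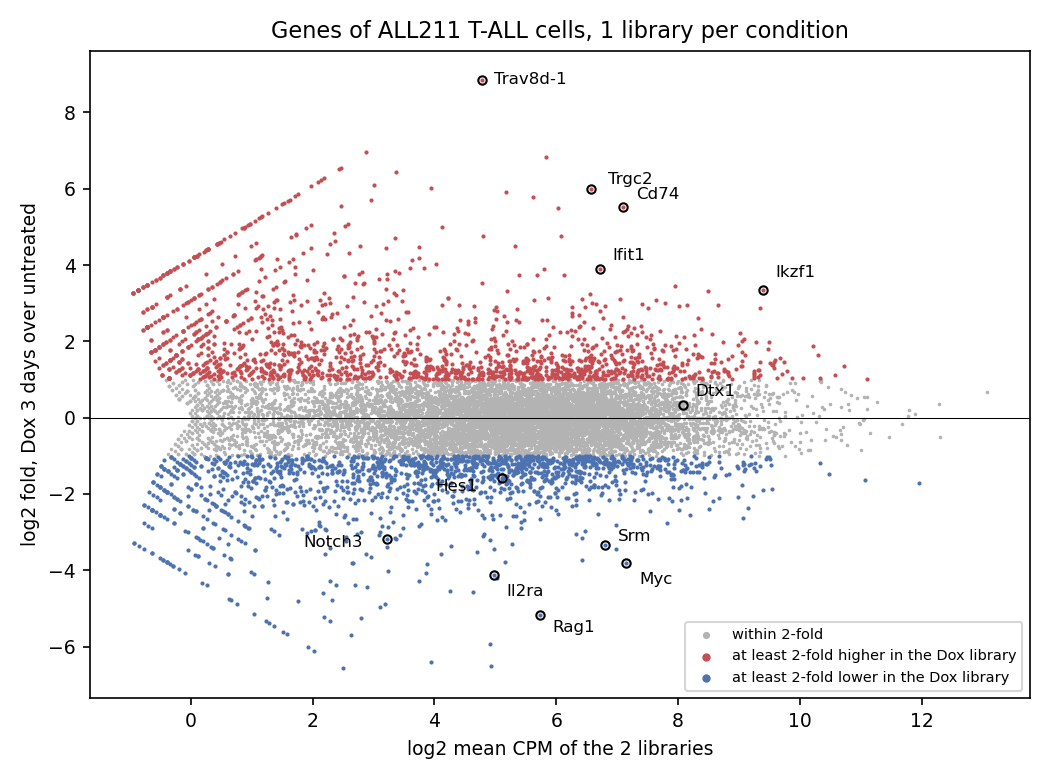
Each point is a gene of the 2 libraries, with the log2 of its mean CPM on the x axis and its log2 fold, Dox over untreated, on the y axis. The 1644 genes at least 2-fold higher in the Dox library are red, the 1581 at least 2-fold lower are blue, and Ikzf1 stands at 3.35 while Myc stands at -3.80.

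Notch target genes were lower on balance in the Dox library. Of 20 measured genes of the fixed list, 11 were at least 2-fold lower, 3 at least 2-fold higher and 6 in between. The list's median log2 fold was -1.24, below every one of 10000 random lists matched on expression (percentile 0). Il2ra, the alpha chain of the interleukin-2 receptor, was 18.1-fold lower (59.6 CPM untreated and 3.30 CPM Dox; log2 fold -4.13, interval -4.60 to -3.78). Myc, a transcription factor that drives growth, was 14.0-fold lower (265.7 and 18.9 CPM; log2 fold -3.80, interval -3.98 to -3.65). Cdk6, a kinase of the G1 phase, had a log2 fold of -3.43 and Notch3, a Notch receptor, was 9.53-fold lower. Hes1, a transcriptional repressor and direct Notch target, was 3.02-fold lower (51.7 and 17.2 CPM). Ptcra, the pre-T-cell receptor alpha chain, had 32 counts in the untreated library and 1 in the Dox library, a ratio of 0.0326 with an interval of 0.0008 to 0.195. The 3 members at least 2-fold higher, named after their values were seen, were the chemokine receptor gene Ccr7 (1.66), Lfng, which encodes a glycosyltransferase that modifies Notch receptors (1.55), and Trib2 (1.16). Dtx1, another Notch target, had a log2 fold of 0.34 (interval 0.28 to 0.40).

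**Figure D2:**
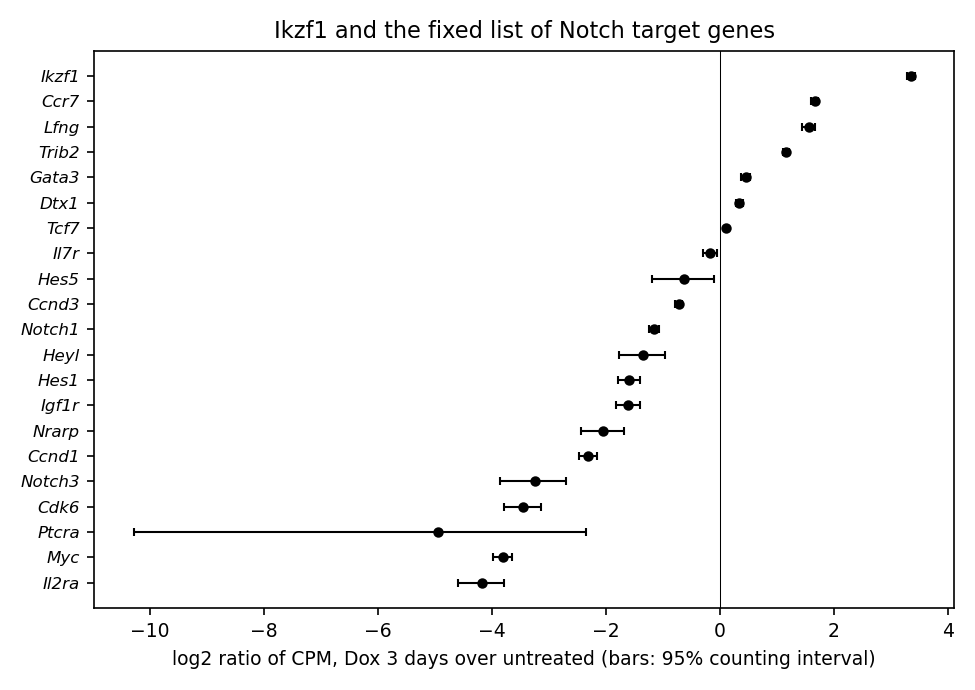
The log2 ratio of CPM, Dox over untreated and without a prior count, is on the x axis for Ikzf1 and the 20 measured Notch target genes, with 1 library per condition. Bars are 95% counting intervals; Il2ra, Myc, Cdk6 and Notch3 lie far to the left of 0, Dtx1 lies to the right of it, and Ptcra, with 32 and 1 counts, has the widest bar.

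Genes of ribosome biogenesis and other Myc-associated growth genes were lower throughout. All 28 measured members had a negative log2 fold, and 26 were at least 2-fold lower (median -1.89, percentile 0). Srm, the spermidine synthase gene, was 10.1-fold lower, from 203.6 to 20.1 CPM (log2 fold -3.33). Gnl3, which encodes nucleostemin, had a log2 fold of -2.81. Cad, which encodes the enzyme of the first steps of pyrimidine synthesis, had a log2 fold of -2.77, and Polr1b, a subunit of RNA polymerase I, -2.52. Ribosomal protein genes differed less: 2 of 26 were at least 2-fold lower, with a median of -0.58 (percentile 0), which was -0.34 after a trend with gene length was removed. Rps2 was 2.17-fold lower. Rpl13 had only 119 and 40 counts, and its level is uncertain because its processed pseudogenes may share reads.

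DNA replication genes were lower, and mitotic genes much less so. Of 28 measured S-phase genes, 23 were at least 2-fold lower and 0 at least 2-fold higher (median -1.24, percentile 0). Tk1, the cytosolic thymidine kinase, had a log2 fold of -1.76, Mcm10, a replication initiation factor, -1.66, the licensing factor gene Cdt1 -1.65, and Mcm2, a subunit of the replicative helicase, -1.57. Of 26 measured G2/M genes, 2 were at least 2-fold lower, Anln (-1.06) and Cdk1 (-1.03), and the median was -0.42 (percentile 0.7). Matched on the untreated level alone, the G2/M percentile was 8.68. The list of cell cycle inhibitors and quiescence genes was higher on balance, with 13 of 20 at least 2-fold higher and 2 at least 2-fold lower (median 1.40, percentile 100). Tob1 and Btg1, antiproliferative proteins of 1 family, had log2 folds of 2.32 and 1.99. The CDK inhibitor genes themselves went both ways. Cdkn2d, which encodes p19, had a log2 fold of 1.78, and of those named after their values were seen, Cdkn1b had 1.73, Cdkn2b 0.96, Cdkn2c 0.10 and Cdkn2a -0.10, while the 2 members at least 2-fold lower were Cdkn1a (-1.20) and Cdkn1c (-1.06).

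Targets of FOXO factors, which PI3K signalling restrains, were higher too: 11 of 18 were at least 2-fold higher and 0 at least 2-fold lower (median 1.39, percentile 100). S1pr1, the sphingosine 1-phosphate receptor used in exit from lymphoid organs, was at 89.9 CPM in the untreated library and 554.7 CPM in the Dox library (log2 fold 2.62). Txnip, a thioredoxin-binding protein, had a log2 fold of 1.86, Bcl2l11, which encodes the pro-apoptotic protein Bim, 1.82, and Foxo1 itself 1.75. Among adhesion and trafficking genes, 11 of 20 were at least 2-fold higher and 2 at least 2-fold lower (median 1.36, percentile 100). Besides S1pr1, the integrin chain Itga4 (2.39) and the gut-homing chemokine receptor Ccr9 (1.88) were higher, and the integrin chain Itgb7 was at 288.9 and 1152 CPM.

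Genes of early T-cell stages and of the mature receptor complex went opposite ways. Of 8 measured genes of receptor gene recombination and the pre-T-cell receptor, 4 were at least 2-fold lower and 1 at least 2-fold higher (median -0.93, percentile 0.69). Limited to genes with at least 5 CPM, the median was -0.31. Rag1, a recombinase subunit, was 37.6-fold lower, from 103.2 to 2.75 CPM (log2 fold -5.17, interval -5.69 to -4.80). Dntt, the terminal transferase gene, was 5.84-fold lower. The fixed list also held Tdrd5, a gene known from germ cells, at -1.18. In contrast, 7 of 22 genes of the T-cell receptor complex and T-cell surface were at least 2-fold higher and 0 at least 2-fold lower (median 0.81, percentile 99.99). Cd52 had a log2 fold of 1.57, the costimulatory receptor gene Cd27 1.54 and the adaptor gene Lcp2 1.23. T-lineage transcription factors had a median of 0.50 (percentile 99.62), with 3 of 20 at least 2-fold higher, Runx3 (2.54), Bach2 (1.55) and Foxp1 (1.03), and 1 at least 2-fold lower, Myb (-1.03).

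Interferon response genes were higher in the Dox library. Of 25 measured, 22 were at least 2-fold higher and 0 at least 2-fold lower (median 2.15, percentile 100). Ifit1 was 15.1-fold higher (13.0 and 196.6 CPM; log2 fold 3.91, interval 3.72 to 4.12). Rsad2, which encodes viperin, had a log2 fold of 3.90 and Mx1, annotated as a transcribed pseudogene, 3.64. Ifit3 had 4.75, although it shares sequence with a near-identical copy. Major histocompatibility complex (MHC) class I genes were higher, with 10 of 15 at least 2-fold higher and 0 at least 2-fold lower (median 1.17, percentile 100). Nlrc5, the transactivator of class I genes, had a log2 fold of 2.96, Tapbp, which encodes tapasin, 1.58, and the class I genes H2-T24 and H2-T23 2.79 and 1.88, with reads that paralogs can share. Markers of macrophages and dendritic cells were higher in the same library, with medians of 2.54 and 4.63.

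Apoptosis genes were mixed. Among 18 pro-apoptotic genes, 5 were at least 2-fold higher and 1 at least 2-fold lower (median 0.18, percentile 81.57). Besides Bcl2l11, the death receptor gene Fas (12.5 and 71.7 CPM) and Bmf (11.8 and 31.9 CPM) were higher, and Fasl was at 8 and 24 counts. Among 12 anti-apoptotic genes, 3 were at least 2-fold higher and 0 lower by that much (median 0.74, percentile 99.27), among them Pim1 (2.07) and Birc3 (1.33), with Mcl1 at 0.92. Bcl2a1a, 1 of several near-identical copies, had 2 and 34 counts, a ratio of Dox to untreated of 17.7 with an interval of 4.54 to 152. Of 19 p53 target genes, 4 were at least 2-fold higher and 2 at least 2-fold lower (median -0.06, percentile 43.2). They included Trp53inp1 (1.90), Bbc3 (1.28) and Aen (-1.29).

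Among metabolic and signalling lists, glycolysis genes had a median of -0.54 (percentile 0.5), with 5 of 20 at least 2-fold lower and 0 at least 2-fold higher. Hk2, a hexokinase, was 8.82-fold lower, Tpi1 3.52-fold, Pgam1 2.66-fold and Pgk1 2.42-fold. Nuclear genes of oxidative phosphorylation had a median of -0.39 (-0.25 after the gene length trend was removed). Their percentile was 2.16, but 14.1 matched on the untreated level alone and 10.96 matched also on gene length, and 1 of 22, Cycs (-1.24), was at least 2-fold lower. Atp5b had -0.83. The 13 mitochondrially encoded genes lay within 2-fold, with a median of 0.53 (percentile 96.63), COX1 at 0.68, and mitochondrial counts made up 2.11% of the untreated and 2.85% of the Dox library. All 20 cholesterol synthesis genes lay within 2-fold (median 0.07, percentile 72.51), with Sc5d at 0.87 and Lss at -0.65. Of 15 genes of the integrated stress response, 7 were at least 2-fold lower and 3 at least 2-fold higher (median -0.78, percentile 0.12). The members lowest in the Dox library serve amino acid supply: Asns (-2.54), the transporter gene Slc7a5 (-2.53), Shmt2 (-2.17) and Phgdh (-1.76). Of 10 heat shock genes, 7 were at least 2-fold lower (median -1.77, percentile 0), among them Hspd1 (928.1 and 149.5 CPM) and Hspe1 (211.4 and 52.9 CPM), the mitochondrial chaperonin pair, Hsp90aa1 (-2.36) and Hsph1 (-2.19). Immediate early genes were higher, with 10 of 16 at least 2-fold higher and 0 at least 2-fold lower (median 1.36, percentile 100). Fos had a log2 fold of 3.74, Zfp36 2.35, Jun 2.28 and Nr4a3, from 4 and 67 counts, 3.57. The macrophage and dendritic cell markers given below were also higher in that library, by medians of 2.54 and 4.63. Of 17 genes of cytokine and STAT5 signalling, 5 were at least 2-fold higher, among them Il4ra (1.43) and Jak1 (1.29), and 2 at least 2-fold lower (median 0.35, percentile 94.92).

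**Figure D3:**
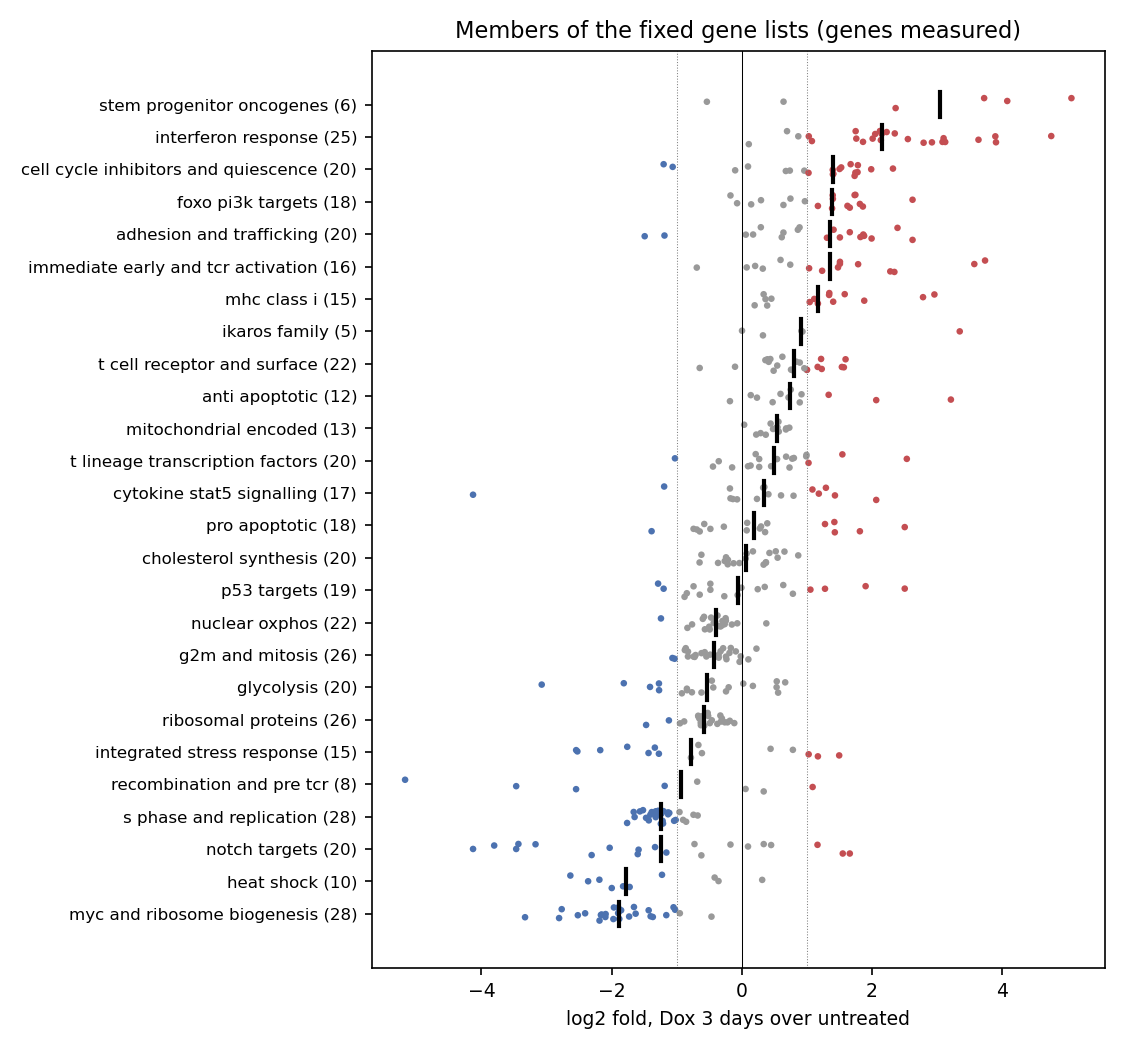
Each point is a measured gene of a fixed list, with its log2 fold, Dox over untreated, on the x axis, and a black bar marks the median of each list; red and blue points are at least 2-fold higher and lower, and lists of other cell types are left out. Medians run from -1.89 for Myc-associated and ribosome biogenesis genes to 3.04 for stem and progenitor oncogenes. Of the 6 measured genes of that last list, the 4 at least 2-fold higher were below 1 CPM in the untreated library.

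Of the 33 lists with enough members for a percentile, 10 lay below the central 95% of random lists and 15 above it. The lists share genes and hold genes regulated together, so this tally describes the lists and is not set against chance. Matched on the untreated level alone, 8 lay below and 15 above, and the lists that left were G2/M, nuclear oxidative phosphorylation, natural killer genes and stem and progenitor oncogenes, while the Ikaros family and mitochondrially encoded genes entered.

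Markers of other cell types were mostly at low levels and higher in the Dox library. In the untreated library, 1 CPM was reached by 8 of 18 measured macrophage, 6 of 10 B-cell list, 5 of 10 erythroid, 2 of 6 natural killer and 2 of 5 neutrophil genes. The remaining genes passed the expression filter through the Dox library alone, which favours higher values in these lists. All 7 measured dendritic cell markers were at least 2-fold higher (median 4.63, percentile 100), and 0 of them reached 1 CPM in the untreated library. Clec9a, a receptor of cross-presenting dendritic cells, had 0 and 129 counts, at least 44.8-fold higher against a floor of 3 counts per library, Siglech, a marker of plasmacytoid dendritic cells, was at least 35.1-fold higher, and Xcr1 had 5 and 165 counts. Itgax, which encodes CD11c, had 2 and 179 counts, a ratio of 93.3 with an interval of 25.5 to 776. Of 18 macrophage markers, 17 were at least 2-fold higher (median 2.54, percentile 100), among them Mpeg1 (1.64 and 96.8 CPM), Tyrobp (0.469 and 11.7 CPM), Cybb (0.469 and 7.02 CPM), C1qa (0.586 and 5.86 CPM) and Itgam (60.6 and 181.0 CPM). Of 10 measured B-cell list genes, 8 were at least 2-fold higher (median 2.79, percentile 99.99), and the median was 5.50 over those with at least 5 CPM. These included the MHC class II genes, which dendritic cells and macrophages also express: Cd74 (5.74 and 268.7 CPM; log2 fold 5.52), H2-Aa (2.70 and 127.5 CPM; 5.50) and H2-Eb1 (0.879 and 112.7 CPM; 6.82). Ighm was at 346.4 CPM in the untreated library and 948.2 CPM in the Dox library, and Jchain, with 0 and 34 counts, was at least 11.8-fold higher.

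Erythroid markers were at least 2-fold higher for 9 of 10 genes (median 2.27, percentile 99.92), at low levels. Hba-a1 had 1.52 and 16.9 CPM, Hba-a2 2.87 and 20.3 CPM, Hbb-b1 1.82 and 18.4 CPM and Slc4a1 0.469 and 2.93 CPM. The globin copies may share reads. Of 6 natural killer and cytotoxic genes, 4 were at least 2-fold higher (median 2.61, percentile 98.13, or 92.68 matched on the untreated level), from few counts. Prf1, with 0 and 39 counts, was at least 13.6-fold higher and Klrk1, with 0 and 28, at least 9.73-fold higher. The abundant Gzma had 2116 and 2798 CPM, Tbx21 had a log2 fold of -0.51, and over genes with at least 5 CPM the list's median was -0.05. The 5 neutrophil markers were under 4 CPM in both libraries (median 1.37, percentile 77.44), with S100a9 at 2.11 and 3.79 CPM and Ngp at 0.351 and 1.95 CPM. Over neutrophil genes with at least 1 count the median was 0.77. Of 5 stromal and endothelial markers, 0 were at least 2-fold higher and 2 at least 2-fold lower (median 0.14, percentile 59.4), Col1a2 (76.4 and 32.9 CPM) and Pdgfrb, with 80 and 2 counts (ratio of Dox to untreated 0.0261, interval 0.0031 to 0.0973); Pecam1 was at 166.3 and 316.8 CPM. Xist was at 191.0 and 167.9 CPM and Uty at 1.05 and 1.22 CPM. No platelet marker passed the expression filter. Among 6 measured stem and progenitor oncogenes, 4 were at least 2-fold higher (median 3.04, percentile 99.98, or 97.31 matched on the untreated level), Kit (4 and 192 counts), Flt3 (12 and 176 counts), Spi1 (4 and 96 counts) and Lmo2 (2 and 18 counts), all of them below 1 CPM in the untreated library. These 4 genes passed the expression filter through the Dox library alone, which favours higher values. The other 2 lay within 2-fold, and the list's summed level was 147.3 CPM in the untreated and 132.0 CPM in the Dox library. Flt3 also stood on the dendritic list, and over all list members with a count the median was 1.61.

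The 15 genes highest in the Dox library included 8 antigen receptor genes. Trav8d-1, a T-cell receptor alpha variable segment, had 0 and 898 counts and was at least 312-fold higher. Traj52 was at least 63.2-fold higher. Of the gamma receptor genes, Trgv4 was at least 61.8-fold higher, Trgc2 had 48 and 3081 counts, Trgv2 18 and 1167, and Trgc1 2 and 337, a ratio of 176 with an interval of 48.2 to 1456. The immunoglobulin genes Igha and Igkv10-96 were at least 84.1-fold and 38.6-fold higher. The others were H2-Eb1, Clec9a, Clec2i, Rnase6, Anpep, Dnase1l3 and Wdfy4. The 15 genes lowest in the Dox library included Rag1 and otherwise genes outside the fixed lists. Ncs1, a neuronal calcium sensor, was at least 61.4-fold lower, Arsi, an arylsulfatase, 110-fold lower (60.6 and 0.549 CPM), Slc4a5 125-fold lower and Dock1, a guanine nucleotide exchange factor, 69.8-fold lower. Fam163b, Fjx1, Stra6, Ccdc153 and Morn4 had 0 counts in the Dox library and were at least 28.1-fold to 44.5-fold lower. Htra1, Rab34 and Sema6a had 2 counts each there, C1qtnf1 had 4, and Ephb4 was 39.3-fold lower. Receptor segments and immunoglobulin genes have close paralogs, so their counts may be split among copies.

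The beta chain repertoire was dominated by 1 segment in both libraries; the segments named here were chosen after their values were seen. Trbv19 took 98.5% of the 22725 Trbv counts in the untreated library (Wilson 95% interval 98.3 to 98.7) and 98.9% of 34690 in the Dox library (98.76 to 98.98). Trav16 took 83.8% of 3089 Trav counts in the untreated library (82.5 to 85.1) and 67.7% of 5253 in the Dox library (66.4 to 68.9). These intervals of shares also treat reads as independent and cover counting error only.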

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

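With 1 library per condition no library could be left out, and no paired analysis was possible because each group has 1 sample. The planned replicated comparison and the use of the series table were not run, the second because its counts are identical. The trends with gene length and GC content and the matching on length were chosen after seeing the data. The log2 fold of Ikzf1 stayed between 3.23 and 3.38, and its value after the gene length trend was removed, 3.23, was the single one outside its counting interval. The count of genes at least 2-fold higher was 2993 with the filter of at least 1 count, 1091 with at least 5 CPM and 541 at the 4-fold threshold. The count lower was 372 at the 4-fold threshold and 1016 where the interval had to lie wholly beyond 2-fold. These follow from how many genes enter or from the size asked for. Of the genes past 2-fold, 51.0% were higher, 59.6% with the filter of at least 1 count, and 47.8% with at least 5 CPM, where 1091 were higher and 1191 lower, so that the balance turned; scaling alternatives gave 49.13% to 52.99%. Without the listed genes of other cell types, 1602 were higher and 1568 lower, while unlisted genes that such cells express stayed in. The sign of a list median changed for 2 lists. Natural killer and cytotoxic genes had -0.0533 with at least 5 CPM, where fewer genes of the list remain. The sex-linked list, a pair of genes with a median of 0.0028 in the main setting, took the other sign under 8 settings. Its lowest median, -0.59, came with the filter of at least 1 count, where more genes of the list enter. In all, 6 values left the interval of their list's median, 4 of them after the gene length trend was removed. Nuclear oxidative phosphorylation genes had -0.25 after the gene length trend was removed, and the cause was not tested. The dendritic median was 6.22 with a prior count of 0.5. Of the members, 4 have 0 untreated counts and Itgax has 2, where the prior count weighs most. At the main prior count of 2, with these 4 at their bound, the median was 4.63. Percentiles that crossed the edge of the central 95% were those of the Ikaros family (97.3; 97.97 with 10 bins and 99.34 matched on the untreated level), mitochondrially encoded genes (96.63; 98.05, 99.82 and, matched also on length, 99.77), stem and progenitor oncogenes (97.31), G2/M (8.68), nuclear oxidative phosphorylation (14.1, and 10.96 matched on length) and natural killer genes (92.68). Of named genes, 63 values moved beyond their counting interval and 1793 did not. Removal of the gene length trend gave 33 of these 63 values, the most of any setting, and a prior count of 5 gave 19. The GC trend had values for 11179 of the 12125 genes.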

Other observations

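All tests below, their bounds, the gene families and the genes named from them were chosen only after the results were seen. The 7 families, picked in this way, are described only and are no test. The GIMAP GTPases of lymphocytes had 6 of 8 genes at least 2-fold higher in the Dox library (median log2 fold 1.57), with Gimap3 at 3.00 and Gimap9 at -0.04. Schlafen genes were at least 2-fold higher for 6 of 8 and at least 2-fold lower for 1 (median 2.20), from Slfn1 (3.44) to Slfn9 (-1.55). Guanylate-binding proteins, which interferon induces, were at least 2-fold higher for 10 of 11 genes (median 2.28). Purine and pyrimidine synthesis genes were at least 2-fold lower for 12 of 15 (median -1.67), among them Atic (-2.11), Gart (-2.12) and Ppat (-1.90). Cad, Tyms and Slfn2 are also on fixed lists. Subunits of the cytosolic chaperonin were at least 2-fold lower for 5 of 8 (median -1.21), and cytosolic tRNA synthetases for 7 of 20 (median -0.78). Core proteasome subunits all lay within 2-fold (median -0.31). Gimap, Schlafen and guanylate-binding genes have close paralogs that can share reads.

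MHC class II and dendritic cell genes were higher in the Dox library, the most abundant of them Cd74 at 268.7 CPM. B cells as the main source of class II are argued against, because Ms4a1, Cd79a and Cd79b together had 34 counts, 0.773% of the 4400 counts of Cd74. Immunoglobulin-expressing cells are not excluded, since Igk counts were 3 and 226, Igh counts outside Ighm 12 and 435, Igha 0 and 242 and Jchain 0 and 34 in the untreated and Dox libraries. Dendritic cells of the recipient, which a GFP sort should remove but a GFP-mid gate may admit more than a GFP-high gate, cannot be told apart from expression by the leukemia cells. The 7 measured dendritic markers, all at least 2-fold higher, do not decide it: they are part of the pattern, 1 (Flt3) is also on another list, and 0 reached 1 CPM in the untreated library, so they passed the expression filter through the Dox library.

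Interferon response genes were higher by a median log2 fold of 2.15, and a trend with gene length or GC content is argued against, since the lowest median after removal of either was 2.18. RNA from recipient cells cannot be told apart from a response of the leukemia cells, because a profile of those cells would have to be assumed. The list gained 3505 CPM, 1.43 times the 2451 CPM gained by all 61 other-cell markers, of which Gzma and Ighm, abundant in the untreated library, gave 1284 CPM; without these 2 genes the ratio was 3.00. Other markers that the untreated library also held stayed in. Among them were Pecam1 (166.3 and 316.8 CPM), Itgam (60.6 and 181.0 CPM) and Col1a2 (76.4 and 32.9 CPM). The marker gains therefore do not measure RNA of recipient cells alone. Dendritic markers gained 48.5 CPM and macrophage markers, with Itgam, 311.8 CPM, and of other versions looked at, 4 interferon genes gained more than the 263 CPM of Cd74. A response to Ikaros, to Dox, or a difference between the mice may each account for it and was not tested.

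T-cell receptor gamma constant genes together were 44.8-fold higher in the Dox library, and Trav8d-1 took 17.1% of Trav counts there against 0 of 3089 in the untreated library. Trbv segments outside Trbv19 gained 3.89 CPM, 1.002% of the summed gain of both (upper counting bound 1.98%). The gamma constant genes gave 333.7 CPM of that sum. It is thus mostly gamma constant RNA, so this small share does not decide on recipient T cells that carry a beta chain. Gamma-delta T cells need no beta chain, so the Trbv gain cannot decide on them. Of the values used in this test only Trdc bears on them, with 1 count in the untreated library and 0 in the Dox library. The annotation used for counting is not given, so these Trdc counts do not exclude gamma-delta T cells. For Trav8d-1 alone, T cells of the recipient are left open, since the bound was 14.0% of its gain. Reads moved from other Trav8 segments are argued against, since these had 2 counts in the untreated library, although 139 in the Dox library leave the split among copies uncertain. A candidate explanation is a leukemic subclone with the same beta chain, or transcription of these loci after Dox, and neither was tested.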
